A study of Homo sapiens with 24 samples.

How the data were processed

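Gene expression was measured in IMR90 cells, human fetal lung fibroblasts with a 4-hydroxytamoxifen-inducible ER:RAS protein, at 8 time points (0, 2, 8 and 24 h, and 2, 4, 6 and 8 d in 100 nM 4-OHT) with 3 biological replicates each (batches A, B and D), on 24 Illumina human-6 v2 BeadChip arrays. Per the labels, cells were passaged the day before harvest, RNA was taken with RNeasy and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The arrays were grouped by the time point and the batch letter of their labels.

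The deposited values of each array are log2 intensities of 48701 probes, between 3.21 and 14.8, and the series matrix holds log2 intensities that the authors quantile-normalized, judged by the values. The series matrix had a Spearman correlation of 1 with the deposited array values and a median absolute difference of 0.00274 to a quantile normalization of them made here. The largest share of identical values in any 2 arrays was 0%. The files used here hold no detection p and no control probes, so the planned correction by control probes (neqc) and the planned filter on detection p were replaced. Deposited values were turned to the linear scale, corrected with the normexp model of limma (saddle estimate) with an offset of 16, put on the log2 scale and quantile-normalized. A background model was made for each array from the mode of its values and the spread of the values below the mode, and a probe counted as above background where the model gave a probability under 0.01. The mode lay between 5.53 and 6.01 on the 24 arrays, and 26.7% to 30.1% of probes were above background.

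Probes were named from the platform's gene symbols, updated through the Entrez ID to RefSeq gene names: 23687 probes had 1 gene symbol, 35 had several and 24979 had none, and these symbols stood for 18774 genes. Of the named probes, 99.7% matched by Entrez ID, and 0 symbols changed. Probes above background on at least 3 arrays were kept (16124), and each gene was read from its kept probe with the highest mean, which left 11007 genes, 1210 of them with more than 1 kept probe. Where a gene was above background on 0 of the 3 arrays of its dimmer group, its fold is given as at least the ratio to the lowest signal above background on those arrays (or its own signal where higher), and where 1 or 2 of them measured it, that number is given.

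Genes were tested with limma on all 24 arrays with 8 group means and no block (16 residual degrees of freedom, 6.72 prior degrees of freedom), with p adjusted by Benjamini-Hochberg within each comparison and a threshold of 0.05. The 9 comparisons were each later time point with 0 h, 4 d with 2 d, and 8 d with 4 d, and the difference between 8 d and 2 d was tested for lists and named genes. The 7 comparisons with 0 h share its 3 arrays, and so share the chance values of those arrays. The batch letters pair the arrays, since the labels give them as biological batches. Residuals of arrays with the same letter had a mean correlation of 0.0365 in batch A (from −0.251 to 0.399), 0.00412 in batch B and 0.0599 in batch D, against −0.0157 between arrays of different letters and time points. Of 3 letters, the own letter had the highest mean correlation over the other time points for 9 of 24 arrays, so the residuals show little sign of the pairing.

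Gene lists were tested with camera (limma) with a preset correlation of 0.01 and p adjusted over the lists of a comparison, for lists with at least 5 measured genes. The 22 lists, written from general knowledge, were autophagy core machinery, lysosome, secretory factors of senescence, G2 and mitosis, DNA replication and G1/S, p53 targets and CDK inhibitors, RAS and ERK output, immediate early genes, mTOR and PI3K negative regulators, senescence chromatin and lamina, fibroblast extracellular matrix, smooth muscle and myofibroblast, cholesterol synthesis, unfolded protein and ATF4 response, interferon response, NF-kB pathway, glycolysis and hypoxia, cytosolic ribosomal proteins, estrogen receptor targets, and markers of epithelial, endothelial and immune cells. Of these, 21 were tested, and the immune list had 3 measured genes. In 10 of 210 list comparisons the median, the mean and the test differed in sign, and 0 of these were called. Counts of members are given by the test over all genes and adjusted over the list alone.

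The genes named are the 12 largest rises and 12 largest falls at 8 d against 0 h, the 6 largest of each kind in the other comparisons, up to 4 called members of each list per comparison, and a fixed set of genes of RAS signalling, the cell cycle, senescence and autophagy. The largest rises and falls had to pass the test, to change the same way in all 3 comparisons of arrays with the same letter, and to be above background on all 3 arrays of at least 1 group. Placeholder symbols (such as those that start with LOC, FLJ, KIAA or MGC, and open reading frames), genes of the Y chromosome and XIST were left out of them. Not every gene that met the rule is described. The other named genes that are said to have risen or fallen also moved the same way in all 3 letters, except RB1 at 8 d. The lists, comparisons, tests, naming rule and alternatives were chosen before the data were examined, apart from the background model, the offset of 16 and the alternatives named as later ones. The alternatives were the batch as a block, only the 2 time points compared, no background correction, median centring, the series matrix values, no or a stricter filter on dim probes, each probe on its own, a 2-fold threshold, an intensity trend with robust variance, array weights, other probes of a gene, an estimated correlation or fry in the list tests, and leaving out each array and each batch. An offset of 50 was chosen after seeing the data. Leaving out 4 d B or 4 d D belongs to leaving out each array, and these were singled out after seeing the data.

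The test was checked on simulated data with 3 arrays per group and 11007 genes, 50 planted at each size: 27 (54%) were called at a log2 change of 0.5, 49 (98%) at 1, and 50 (100%) at 2 and at 3. The 51 lysosome genes were raised by 0.5 in the same data, and their calls count among all calls. Of the unchanged genes 7 were called (3.32% of calls), and 0 were called in a comparison with none planted. Where as few genes change as in these data, single genes that changed by 0.5 or less are often missed with 3 arrays per time point. At 8 d 5221 of 11007 genes passed, which makes the adjustment of p less strict, and the share missed there was not tested. In the simulated data each gene had the same spread at all time points, and genes varied independently. The real spread can be wider at 4 d, so the share of false calls in comparisons with 4 d was not tested. Computations used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.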

Results

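The arrays follow IMR90 cells, a line of human fetal lung fibroblasts, that carry RAS fused to the estrogen receptor and were given 100 nM 4-hydroxytamoxifen (4-OHT). Cells were taken at 0, 2, 8 and 24 h and at 2, 4, 6 and 8 d, with 3 arrays per time point from biological batches A, B and D (24 arrays, 11007 genes tested). Gene values below are log2 fold changes ± standard error with n = 3 arrays per time point. The standard error comes from the fit of all 24 arrays, with 1 estimate of the spread per gene shared by all time points. It is not the spread of the 3 arrays compared, which can be wider, above all at 4 d. DKK1 at 4 d against 0 h, for example, was −4.11 in batch A, −5.48 in batch B and −2.51 in batch D. The first principal component held 65.1% of the variance and placed the 0 h to 24 h arrays between −34.7 and −23.9, the 2 d arrays between −13.5 and −8.88, and the 6 d and 8 d arrays between 41.3 and 51.2. The 4 d arrays lay apart from one another, at 33.6 (batch A), 46.7 (batch B) and 24.9 (batch D). Untreated arrays at later time points were not analysed here, so each comparison with 0 h holds the 4-OHT, the RAS protein and the time in culture together. Fewer genes passed the test against 0 h at 2 h and 8 h than at 4 d, 6 d and 8 d.

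**Figure D1:**
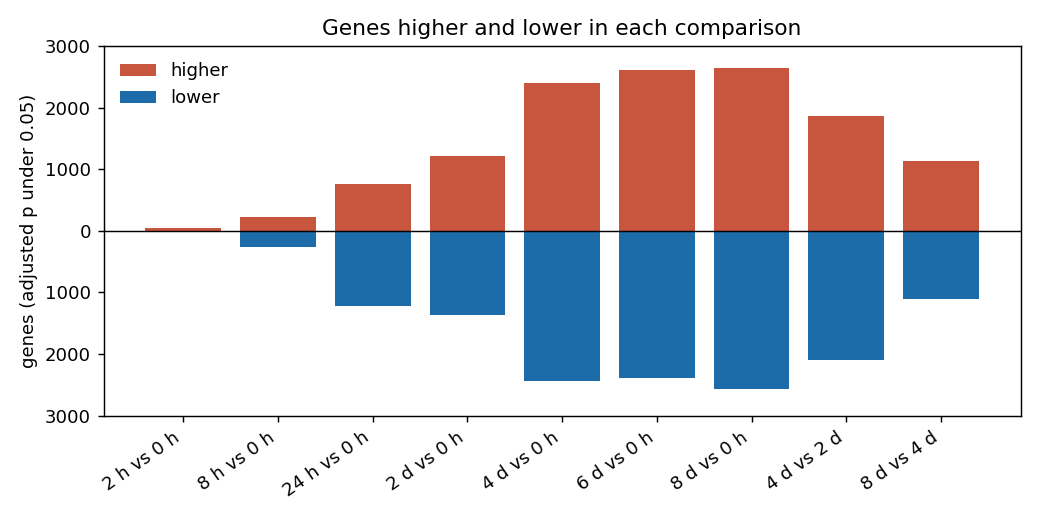
Number of genes higher and lower in each of the 9 comparisons (limma, adjusted p under 0.05, 3 arrays per time point).

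Was a RAS gene or the receptor itself seen to move? HRAS was 0.41 ± 0.14 above 0 h at 24 h (adjusted p = 0.0427), and at the other time points it lay between −0.18 and 0.28 of 0 h with no call. The 24 h call of HRAS was lost with median centring (0.25, adjusted p = 0.553) and without 0 h A (0.42, adjusted p = 0.0807), 0 h B (0.44, 0.0668), 0 h D (0.37, 0.145), 24 h A (0.36, 0.138), 24 h B (0.30, 0.208), batch A (0.37, 0.276) or batch B (0.32, 0.295). The labels do not say which RAS gene the construct carries, and whether its probes or that of ESR1 match the construct is not given in the sources used here. ESR1 was above background on 0 of 24 arrays.

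What changed in the first 2 h of 4-OHT? LIF, a secreted cytokine, rose 4.71-fold (2.24 ± 0.28), EGR1, an early transcription factor, 3.04-fold (1.60 ± 0.21), and BHLHE40, a transcriptional repressor, 3.64-fold (1.86 ± 0.21). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 3.56-fold (1.83 ± 0.20) and TRIB1, a pseudokinase, 2.72-fold (1.44 ± 0.18). Among the falls were KBTBD7 (−0.91 ± 0.12) and PPP1R3C, which targets protein phosphatase 1 to glycogen (−1.34 ± 0.19). Of 26 measured genes of RAS and ERK output, 9 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.50 (camera, adjusted p = 1.7e-25; adjusted p = 0.00141 with an estimated correlation). Of 28 immediate early genes, 8 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.38 (adjusted p = 1.4e-22; adjusted p = 0.00422 with an estimated correlation). This list shares DUSP1, EGR1, FOSL1, IER3 and MYC with that of RAS and ERK output, so their results are not independent. Genes of G2 and mitosis had a median of −0.30, with 1 of 49 falling (1 adjusted over the list alone; adjusted p = 1.8e-08; adjusted p = 0.575 with an estimated correlation). IL6 was 2.82-fold above 0 h without passing (adjusted p = 0.0574; 0.0126 with the batch as a block).

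By limma, 69 genes changed at 2 h (47 higher, 22 lower), 22 of them by at least 2-fold, and 8 of 21 lists passed with the preset correlation and 2 with an estimated one. Of these, 68.1% were higher, against 56.5% with median centring. The count was 45 without 0 h A, 39 without 0 h B, 44 without 0 h D, 33 without 2 h A, 33 without 2 h B, 125 without 2 h D, 13 without batch B, 151 without batch D and 1 without batch A. That 1 gene was ANGPTL4 (1.74, adjusted p = 0.0181). With all arrays ANGPTL4 was 1.83 by the probe used and 0.51 by its other probe (adjusted p = 0.298). Without batch A the values were 2.24 for LIF (adjusted p = 0.108), 1.54 for EGR1 (0.126), 1.70 for BHLHE40 (0.0939), 1.36 for TRIB1 (0.108), −0.94 for KBTBD7 (0.108) and −1.46 for PPP1R3C (0.108; −1.21 and 0.116 without batch B).

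Which genes followed by 8 h? ESM1, a secreted proteoglycan, rose 7.60-fold (2.93 ± 0.28), TAGLN3 6.36-fold (2.67 ± 0.23), HAS2, a hyaluronan synthase, 3.63-fold (1.86 ± 0.29, 1.26, 1.91 and 1.44 by its other probes), and NTSR1, the neurotensin receptor, 2.89-fold (1.53 ± 0.14). SMAD6, an inhibitor of BMP signalling, fell 3.56-fold (−1.83 ± 0.25) and MXD4, a partner of MAX that opposes MYC, 2.62-fold (−1.39 ± 0.18). Of the 26 genes of RAS and ERK output, 9 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.47 (camera, adjusted p = 1.9e-11; adjusted p = 0.0560 with an estimated correlation). SPRY2 (1.28 ± 0.23) and DUSP5 (1.29 ± 0.22), both feedback inhibitors of the pathway, were among them. Of 15 negative regulators of mTOR and PI3K, 2 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of −0.18 (adjusted p = 0.00504; adjusted p = 0.178 with an estimated correlation): DDIT4 (−1.98 ± 0.38) and PIK3IP1 (−0.91 ± 0.18). STC2, a secreted glycoprotein induced by estrogen receptor, fell by 0.81 ± 0.11. In all, 499 genes changed (231 higher, 268 lower), 46 of them by at least 2-fold, and 7 of 21 lists passed with the preset correlation and 0 with an estimated one.

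The count at 8 h was 303 without 0 h A, 191 without 0 h D, 280 without 8 h A, 215 without 8 h B, 137 without batch B and 28 without batch A. Without batch A the calls of SPRY2 (1.28, adjusted p = 0.137), DUSP5 (1.30, 0.119), DDIT4 (−2.29, 0.101) and PIK3IP1 (−1.05, 0.119) were lost.

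What fell by 24 h? The largest falls were of CEMIP, which takes part in hyaluronan breakdown (13.4-fold; −3.75 ± 0.53), IL6 (4.97-fold; −2.31 ± 0.36), SMAD6 (−2.24 ± 0.25) and IGFBP3, which binds insulin-like growth factors (−2.21 ± 0.31). The chemokine CXCL8 fell by 2.13 ± 0.31. ESM1 (2.89 ± 0.28), NTSR1 (2.76 ± 0.14), TAGLN3 (2.61 ± 0.23) and ITPKA, an inositol trisphosphate kinase (2.36 ± 0.22), were among the largest rises, and LCE2A, a protein of the skin's cornified envelope, rose at least 4.29-fold. Of 31 fibroblast matrix genes, 20 fell and 0 rose (22 and 1 adjusted over the list alone), with a median of −0.59 (camera, adjusted p = 1.9e-13; adjusted p = 0.0125 with an estimated correlation), among them COL3A1 (−1.69 ± 0.17), COL4A1 (−1.63 ± 0.11) and COL1A1 (−1.44 ± 0.11). Of 12 smooth muscle and myofibroblast genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of −0.39 (adjusted p = 0.00144; adjusted p = 0.227 with an estimated correlation). Of 15 estrogen receptor targets, 7 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of −0.30 (adjusted p = 0.000175; adjusted p = 0.00762 with an estimated correlation), among them STC2 (−1.36 ± 0.11) and IGFBP4 (−0.89 ± 0.15).

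Signalling and division genes moved at 24 h as well. Of 22 genes of the NF-kB pathway, 10 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of −0.34 (adjusted p = 0.000642; adjusted p = 0.246 with an estimated correlation), including NFKBIA, the pathway's inhibitor (−1.04 ± 0.17), and CEBPD (−1.44 ± 0.23). Of 49 genes of G2 and mitosis, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.41 (adjusted p = 7.3e-08; adjusted p = 0.456 with an estimated correlation), among them the mitotic kinases PLK1 (1.07 ± 0.16) and NEK2 (0.97 ± 0.20). Of the 28 immediate early genes, 12 fell and 3 rose (13 and 4 adjusted over the list alone), with a median of −0.11 (adjusted p = 0.0206; adjusted p = 0.501 with an estimated correlation), a call lost without 0 h A (−0.09, adjusted p = 0.0686) or batch B (−0.09, 0.0783). HMGA2, a chromatin protein of senescent cells, rose (1.02 ± 0.17). By limma, 1979 genes changed (752 higher, 1227 lower), 227 by at least 2-fold, and 10 of 21 lists passed with the preset correlation and 2 with an estimated one. The share of higher genes was 38.0%, against 10.5% with median centring. The count was 1253 without 0 h D, 663 without batch A and 1115 without batch B.

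What had changed by 2 d? SLC6A15, an amino acid transporter, rose 15.6-fold (3.96 ± 0.14, 2.97 and 2.02 by its other probes), ITPKA 8.75-fold (3.13 ± 0.22) and CNIH3 5.62-fold (2.49 ± 0.18). The cytokines IL1B (2.27 ± 0.30, 1 of 3 arrays above background at 0 h) and LIF (1.64 ± 0.28) rose, and so did CDKN2A, the locus of p16 and ARF (0.94 ± 0.21). IGFBP3 fell 12.2-fold (−3.61 ± 0.31), CEMIP 12.1-fold (−3.59 ± 0.53) and ANKRD1 at least 7.85-fold. Of the 31 matrix genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of −0.79 (camera, adjusted p = 3.2e-17; adjusted p = 0.00415 with an estimated correlation), among them LUM (−2.45 ± 0.15) and DCN (−1.98 ± 0.22), both proteoglycans that bind collagen. Of the 12 smooth muscle genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of −0.94 (adjusted p = 1.8e-08; adjusted p = 0.00793 with an estimated correlation), led by CNN1 (−2.24 ± 0.20) and ACTA2 (−2.16 ± 0.16). Of the 15 estrogen receptor targets, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of −0.50 (adjusted p = 4.0e-06; adjusted p = 0.00185 with an estimated correlation).

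Growth and sterol genes parted at 2 d. Of 47 genes of DNA replication and G1/S, 30 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of −0.58 (adjusted p = 2.6e-12; adjusted p = 0.288 with an estimated correlation), including E2F2 (−2.01 ± 0.18), TYMS, thymidylate synthase (−1.23 ± 0.18), and MCM6 (−1.09 ± 0.13). Of 49 genes of G2 and mitosis, 18 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of −0.49 (adjusted p = 5.5e-07; adjusted p = 0.488 with an estimated correlation). Of 19 genes of cholesterol synthesis, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.67 (adjusted p = 5.6e-07; adjusted p = 0.231 with an estimated correlation), among them MSMO1 (1.42 ± 0.20) and NSDHL (1.10 ± 0.16). By limma, 2581 genes changed (1210 higher, 1371 lower), 367 by at least 2-fold, and 11 of 21 lists passed with the preset correlation and 3 with an estimated one. The share of higher genes was 46.9%, against 20.6% with median centring. The count was 867 without batch A and 1332 without batch B.

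**Figure D2:**
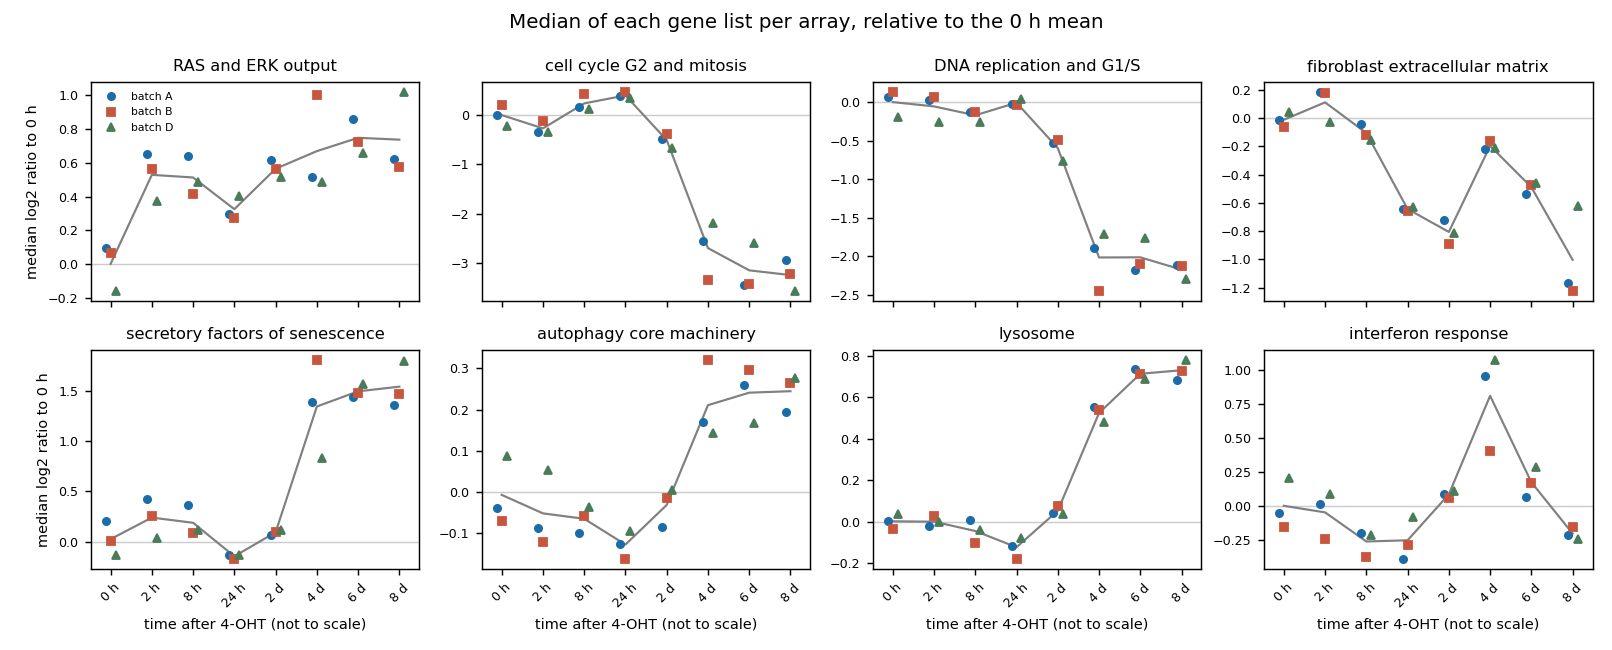
Median log2 ratio to 0 h of 8 gene lists on each array, by batch. The line joins the means of the 3 arrays.

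Between 2 d and 4 d, how did the cells part from their earlier state? IL6 rose 45.6-fold (5.51 ± 0.36), CXCL1, a neutrophil chemokine, 56.1-fold (5.81 ± 0.32), IL1B 37.4-fold (5.22 ± 0.30) and PTGS2, the inducible cyclooxygenase, 31.5-fold (4.98 ± 0.47). The mitotic genes CDC20 (−3.13 ± 0.34), PBK (−3.00 ± 0.30) and CEP55 (−2.87 ± 0.30) fell. Of 49 genes of G2 and mitosis, 49 fell (49 adjusted over the list alone), with a median of −2.01 (camera, adjusted p = 2.0e-32; adjusted p = 0.0553 with an estimated correlation). Of 46 secretory factors of senescence, 31 rose and 2 fell (32 and 2 adjusted over the list alone), with a median of 1.25 (adjusted p = 2.0e-15; adjusted p = 0.0553 with an estimated correlation). Of 51 lysosome genes, 29 rose and 3 fell (33 and 3 adjusted over the list alone), with a median of 0.37 (adjusted p = 2.6e-09; adjusted p = 0.00215 with an estimated correlation), including the protease genes CTSK (1.79 ± 0.19) and CTSO (1.45 ± 0.20). Of the 22 NF-kB genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.80 (adjusted p = 2.6e-09; adjusted p = 0.0209 with an estimated correlation).

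Matrix genes, which fell at 2 d, rose from 2 d to 4 d. Of the 31, 18 rose and 3 fell against 2 d (18 and 3 adjusted over the list alone), with a median of 0.50 (adjusted p = 3.7e-07; adjusted p = 0.0553 with an estimated correlation), among them LUM (2.03 ± 0.15), COL3A1 (1.92 ± 0.17) and COL4A1 (1.86 ± 0.11). The interferon genes IFI6 (2.09 ± 0.13) and IFIH1, a sensor of double-stranded RNA (1.52 ± 0.14, 2 of 3 arrays above background at 2 d), rose with the list (11 of 19 rose, 1 fell; 12 and 1 adjusted over the list alone; median 0.50, adjusted p = 8.5e-05; adjusted p = 0.182 with an estimated correlation). Of 22 genes of senescence chromatin and lamina, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of −0.76 (adjusted p = 2.6e-09; adjusted p = 0.0209 with an estimated correlation), including LMNB1, lamin B1 (−1.89 ± 0.28), and CHAF1B, a histone chaperone (−2.05 ± 0.17). By limma, 3969 genes changed (1866 higher, 2103 lower), 688 by at least 2-fold, and 16 of 21 lists passed with the preset correlation and 3 with an estimated one. The count was 2310 without batch A and 1967 without batch B.

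Against 0 h, which genes stood out at 4 d? IL1B (7.49 ± 0.30) and CST1, a cystatin (5.30 ± 0.38), rose, each above background on 1 of 3 arrays at 0 h. IL1A rose at least 55.6-fold and CXCL1 71.8-fold (6.17 ± 0.32). KLF2, a transcription factor, fell 16.8-fold (−4.07 ± 0.18), DKK1, a WNT inhibitor, 16.4-fold (−4.03 ± 0.35) and OXTR, the oxytocin receptor, 14.1-fold (−3.82 ± 0.14). The CDK inhibitors CDKN2B (3.74 ± 0.26, 0.70 by its other probe), CDKN2A (1.77 ± 0.21) and CDKN1A (1.28 ± 0.13, 0.83 by its other probe) rose. Of 32 p53 targets and CDK inhibitors, 16 rose and 5 fell (16 and 5 adjusted over the list alone), with a median of 0.28 (camera, adjusted p = 0.00148; adjusted p = 0.138 with an estimated correlation). Of the 19 interferon genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.000115; adjusted p = 0.191 with an estimated correlation), among them ISG15 (1.25 ± 0.15) and IFI6 (1.24 ± 0.13). Of 27 genes of glycolysis and hypoxia, 14 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 0.63 (0.67 on array A, 0.76 on B and 0.16 on D; adjusted p = 0.00201; adjusted p = 0.178 with an estimated correlation), including ALDOC (1.45 ± 0.17) and HK2, a hexokinase (1.24 ± 0.15). By limma, 4834 genes changed (2394 higher, 2440 lower), 1080 by at least 2-fold, and 14 of 21 lists passed with the preset correlation and 4 with an estimated one. The share of higher genes was 49.5%, against 37.3% with median centring. The count was 3102 without batch A and 3120 without batch B.

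At 6 d secreted factors were again among the largest rises. IL1B (8.42 ± 0.30) and CCL20, a chemokine (6.03 ± 0.37), rose, each above background on 1 of 3 arrays at 0 h, CXCL1 rose 121-fold (6.92 ± 0.32) and CXCL5 at least 83.3-fold. ASPM, a spindle gene, fell (−4.29 ± 0.37, 2 of 3 arrays above background at 6 d) and NREP fell 16.4-fold (−4.04 ± 0.16). Of 51 lysosome genes, 39 rose and 2 fell (40 and 3 adjusted over the list alone), with a median of 0.76 (camera, adjusted p = 6.1e-11; adjusted p = 0.000805 with an estimated correlation), among them NEU1, a sialidase (1.73 ± 0.14), and CTSK (1.41 ± 0.19). Of the 12 smooth muscle genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of −1.22 (adjusted p = 1.0e-07; adjusted p = 0.0222 with an estimated correlation), among them CNN1 (−3.32 ± 0.20, 1 of 3 arrays above background at 6 d) and ACTG2 (−3.15 ± 0.29). Of the 19 cholesterol genes, 10 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.64 (adjusted p = 0.00203; adjusted p = 0.322 with an estimated correlation). By limma, 4988 genes changed (2604 higher, 2384 lower), 1251 by at least 2-fold, and 12 of 21 lists passed with the preset correlation and 4 with an estimated one. The share of higher genes was 52.2%, against 30.4% with median centring. The count was 3278 without batch A.

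What did 8 d of 4-OHT leave? Secreted factors were among the largest rises: IL1B rose by 8.52 ± 0.30, from 5.49 ± 0.18 to 14.01 ± 0.09 (log2 intensity, mean ± SD, n = 3), and CST1 by 7.05 ± 0.38, each above background on 1 of 3 arrays at 0 h. CXCL1 rose 101.7-fold (6.67 ± 0.32), IL6 42.5-fold (5.41 ± 0.36) and PTGS2 43.8-fold (5.45 ± 0.47). CXCL5 rose at least 101.2-fold, IL1A at least 73.2-fold and CXCL2 at least 29.5-fold. GABRA2, a GABA receptor subunit, rose 26.3-fold (4.72 ± 0.10). Of 46 secretory factors of senescence, 33 rose and 4 fell (33 and 4 adjusted over the list alone), with a median of 1.48 (camera, adjusted p = 1.1e-10; adjusted p = 0.1002 with an estimated correlation). Of 22 NF-kB genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.88 (adjusted p = 4.4e-07; adjusted p = 0.0454 with an estimated correlation), among them IRAK2, a kinase of interleukin-1 signalling (2.63 ± 0.14), and TNFAIP3, an inhibitor of the pathway (2.08 ± 0.17). Of 26 genes of RAS and ERK output, 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.72 (adjusted p = 1.0e-05; adjusted p = 0.0963 with an estimated correlation), including the phosphatases DUSP4 (4.27 ± 0.16, 1.35 by its other probe) and DUSP6 (2.72 ± 0.30). As written, this list and that of secretory factors both hold LIF, IL11, AREG, EREG and PLAUR, so their results are not independent.

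Division and chromatin genes were lower at 8 d than at 0 h. Of 49 genes of G2 and mitosis, 49 fell (49 adjusted over the list alone), with a median of −3.26 (adjusted p = 1.1e-31; adjusted p = 0.0513 with an estimated correlation), including CCNA2, cyclin A2 (−3.67 ± 0.32), CCNB1, cyclin B1 (−2.78 ± 0.24), and TOP2A (−4.00 ± 0.40). Of 47 genes of DNA replication, 43 fell and 0 rose (43 and 0 adjusted over the list alone), with a median of −2.09 (adjusted p = 4.0e-27; adjusted p = 0.0513 with an estimated correlation), among them TK1, thymidine kinase (−3.78 ± 0.20, 2 of 3 arrays above background at 8 d). MKI67 was at least 1.755-fold lower. Of 22 genes of senescence chromatin and lamina, 15 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of −1.22 (adjusted p = 1.1e-07; adjusted p = 0.0445 with an estimated correlation), among the falls LMNB1 (−3.54 ± 0.28) and HMGB2 (−3.59 ± 0.19, 1 of 3 arrays above background at 8 d). HMGA2 rose (1.16 ± 0.17) and HMGA1 was at 0.11 ± 0.11 (adjusted p = 0.427). CDKN2B (2.71 ± 0.26, 0.41 by its other probe), CDKN2A (2.08 ± 0.21) and CDKN1A (1.12 ± 0.13, 0.535 by its other probe) rose, and the list of p53 targets held 15 rises and 9 falls among 32 (15 and 9 adjusted over the list alone; median 0.18, −0.07 with median centring; adjusted p = 0.144). RB1 was lower by the mean of the arrays (−0.69 ± 0.18), but did not fall in all 3 batches. Its call was lost without batch A (−0.51, adjusted p = 0.117) or batch B (−0.48, 0.145). FOSL1 fell (−0.80 ± 0.14).

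**Figure D3:**
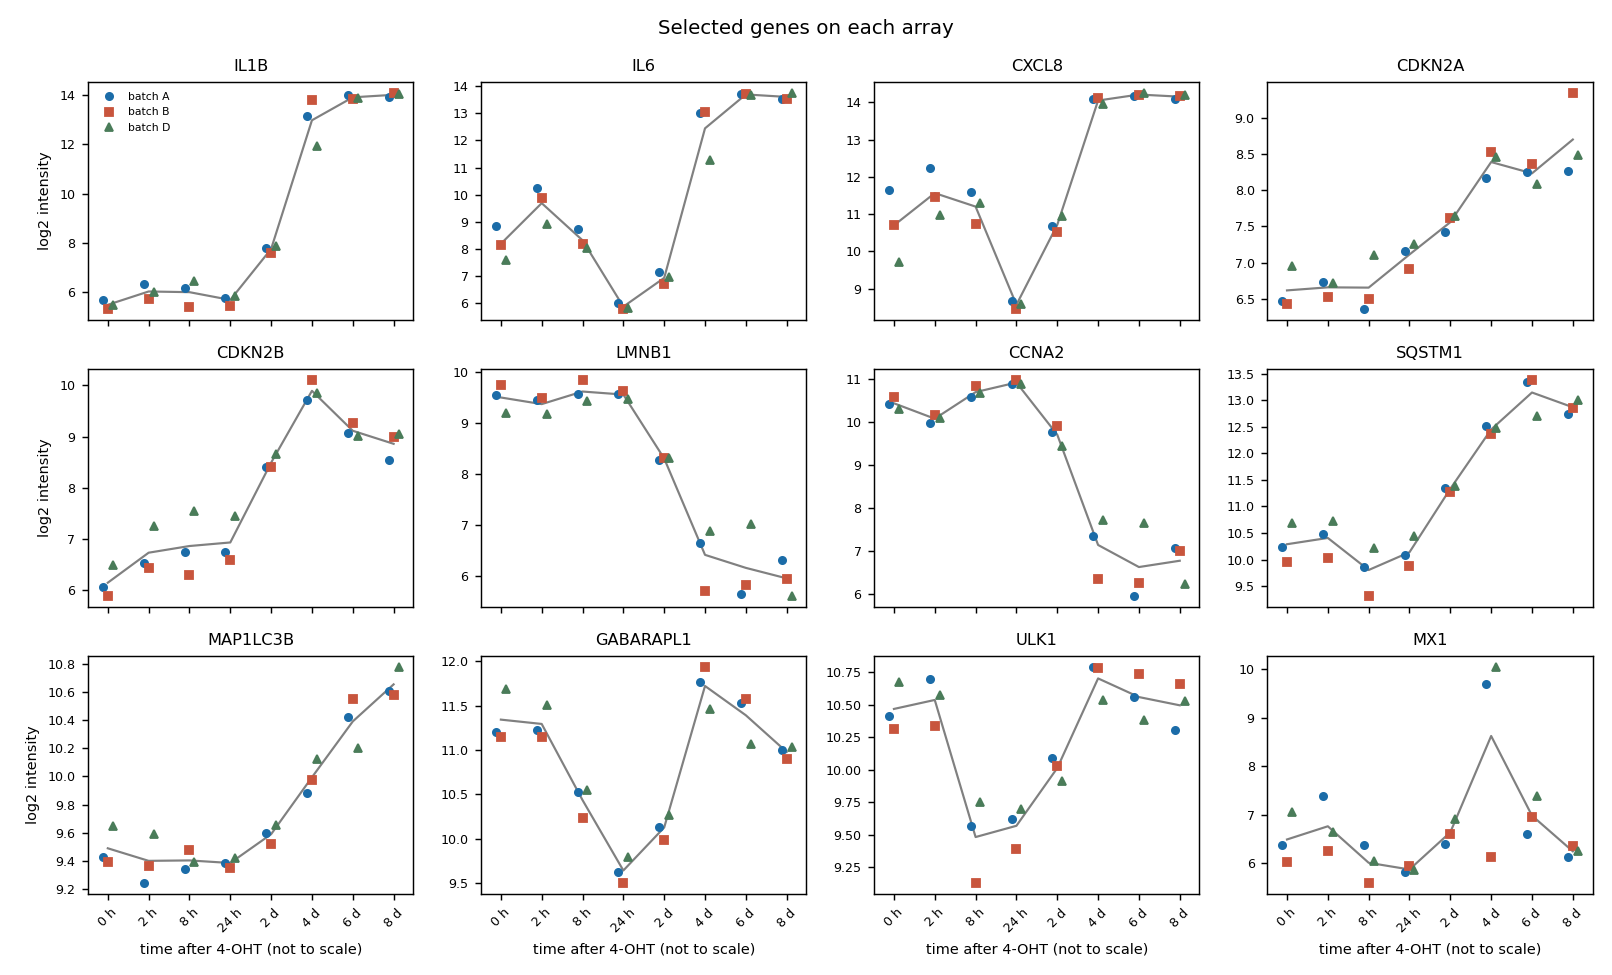
Log2 intensity of 12 genes on each of the 24 arrays, by batch.

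Structural and lysosomal genes complete the 8 d picture. FBLN1, a matrix glycoprotein, fell 20.1-fold (−4.33 ± 0.22, −3.61 and −2.45 by its other probes), NREP 24.1-fold (−4.59 ± 0.16), and COL15A1 at least 15.1-fold. Of 31 matrix genes, 19 fell and 2 rose (20 and 3 adjusted over the list alone), with a median of −1.06 (adjusted p = 1.2e-07; adjusted p = 0.0513 with an estimated correlation). Of 12 smooth muscle genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of −1.24 (adjusted p = 5.9e-06; adjusted p = 0.0445 with an estimated correlation), including CNN1 (−3.02 ± 0.20) and ACTA2 (−2.70 ± 0.16). Of 51 lysosome genes, 39 rose and 3 fell (40 and 3 adjusted over the list alone), with a median of 0.73 (adjusted p = 1.1e-10; adjusted p = 0.000856 with an estimated correlation): NEU1 (1.56 ± 0.14) and ATP6V1C1, a proton pump subunit (1.46 ± 0.17), rose, CTSS rose at least 6.63-fold, and CTSC, a protease gene, fell (−1.78 ± 0.13). By limma, 5221 genes changed (2645 higher, 2576 lower), 1316 by at least 2-fold, and 12 of 21 lists passed with the preset correlation and 4 with an estimated one. The share of higher genes was 50.7%, against 27.3% with median centring.

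Did markers of other cell types move? Of 7 epithelial markers, 4 fell and 0 rose at 8 d (5 and 0 adjusted over the list alone), with a median of −0.47 (adjusted p = 0.0181; adjusted p = 0.113 with an estimated correlation; −0.11 and 0.0964 with no detection filter), KRT19 by at least 1.07-fold. The value depended on the probe for MUC1 (−1.11 ± 0.13, 0.0453 by its other probe) and KRT18 (−0.47 ± 0.13, 0.0580 and −0.28 by its other probes). KRT18 lost its call without batch A (−0.51, adjusted p = 0.0596) or batch B (−0.40, 0.0543). The epithelial list passed at 4 d too (4 of 7 fell, 4 adjusted over the list alone, median −0.44, adjusted p = 0.0254; adjusted p = 0.154 with an estimated correlation), a call lost with no detection filter (−0.05, 0.113) and without batch B (−0.33, 0.0700). It fell at 6 d as well (6 of 7 fell, 6 adjusted over the list alone, median −0.61, adjusted p = 0.00590; adjusted p = 0.0841 with an estimated correlation). At 2 d its median was −0.33 (adjusted p = 0.0498), and it did not pass with an estimated correlation. The 2 d call was lost with no background correction (−0.22, 0.0636), median centring (−0.38, 0.111), the series matrix values (−0.22, 0.0644), no detection filter (−0.13, 0.0811), array weights (−0.26, 0.0809) and an offset of 50 (−0.19, 0.0614). Leaving out 0 h B (−0.21, 0.130), 0 h D (−0.28, 0.0603), 2 d A (−0.25, 0.0827), 2 d B (−0.37, 0.0584), batch B (−0.25, 0.208) or batch D (−0.37, 0.0618) ended it too. Of 8 endothelial markers, at 8 d 3 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.216, and 0.20 and 0.04995 with median centring). The endothelial list passed between 2 d and 4 d (median 0.29, adjusted p = 0.0124; adjusted p = 0.0572 with an estimated correlation). Between 2 d and 8 d it passed too (0.38, adjusted p = 0.0441; adjusted p = 0.142 with an estimated correlation), a call lost with no background correction (0.25, 0.0539), with the series matrix values (0.25, 0.0536) and without 8 d B (0.32, 0.0608) or batch B (0.33, 0.0756). Against 0 h it did not pass at any time point, though with median centring it did at 2 h (0.03, 0.00839), 4 d (0.26, 0.0384) and 6 d (0.19, 0.0294), as at 8 d. With no detection filter it passed at 6 d too (0.22, 0.0304). Of 3 measured immune markers, too few for the test, 1 rose at 24 h (median 0.25) and 2 rose at 2 d (0.79), 4 d (0.46), 6 d (0.65) and 8 d (0.39). CD68, a lysosomal membrane protein abundant in macrophages, was among them at 8 d (0.99 ± 0.11).

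Between 4 d and 8 d a further set of genes changed. SAA2, an acute phase protein (3.53 ± 0.19), PI3, an elastase inhibitor (3.51 ± 0.27), and SERPINB4 (3.47 ± 0.25) rose, each above background on 1 of 3 arrays at 4 d. EDN1, endothelin 1, rose 7.04-fold (2.82 ± 0.26). TNFAIP6, which binds hyaluronan, fell 7.97-fold (−3.00 ± 0.19), and GPC6, a glypican, 6.62-fold (−2.73 ± 0.19, −0.89 by its other probe). Of 31 matrix genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of −0.47 (camera, adjusted p = 1.1e-11; adjusted p = 0.0440 with an estimated correlation), among them POSTN, periostin (−2.05 ± 0.20), and COL3A1 (−2.01 ± 0.17). Of 19 interferon genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of −0.77 (adjusted p = 2.0e-10; adjusted p = 0.0886 with an estimated correlation), among them IFITM1 (−1.91 ± 0.22) and IFI44 (−1.62 ± 0.20). MYC rose (0.97 ± 0.11) and EGR1 fell (−1.16 ± 0.21). By limma, 2239 genes changed (1134 higher, 1105 lower), 300 by at least 2-fold, and 9 of 21 lists passed with the preset correlation and 1 with an estimated one. The share of higher genes was 50.7%, against 25.0% with median centring. The count was 855 without batch A and 1161 without batch B.

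How did genes of autophagy move through the time course? GABARAPL1, which encodes a protein of the autophagosome membrane, fell by 1.70 ± 0.16 at 24 h and by 1.22 ± 0.16 at 2 d, and was 1.60 ± 0.16 higher at 4 d than at 2 d. ULK1, the kinase that starts autophagy, fell by 0.90 ± 0.15 at 24 h and was 0.69 ± 0.15 higher at 4 d than at 2 d. At 8 d the cargo receptor gene SQSTM1 rose (2.58 ± 0.22), as did MAP1LC3B (1.16 ± 0.11), BNIP3L, a receptor for mitochondria (2.30-fold), and ATG7 (0.84 ± 0.15), while ATG5, which takes part in lipidation of the LC3 family, fell (−0.82 ± 0.14). ULK1 was at 0.03 ± 0.15 of 0 h at 8 d (adjusted p = 0.898) and ULK2 had fallen at 6 d (−0.65 ± 0.12). BECN1 rose at 8 d (0.31 ± 0.10), a call lost with median centring (0.04, adjusted p = 0.866) and without batch A (0.34, 0.0773) or batch B (0.34, 0.0677). ULK3, above background on 7 of 24 arrays, was at least 1.097-fold higher at 8 d than at 0 h (adjusted p = 0.0313), a call lost without 0 h B (adjusted p = 0.0980), 0 h D (0.0833), 8 d D (0.228), batch B (0.134) or batch D (0.187). MTOR (0.22 ± 0.11, adjusted p = 0.0985) and TSC2 (0.22 ± 0.11, adjusted p = 0.0967) did not pass at 8 d.

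How did the 46 autophagy genes move as a list? At 24 h 9 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of −0.10 (camera, adjusted p = 0.0639; adjusted p = 0.503 with an estimated correlation), and the list passed without 0 h A (−0.12, 0.0381), 0 h B (−0.15, 0.0278), 24 h D (−0.15, 0.0324) or batch B (−0.12, 0.0472). At 2 d 7 rose and 8 fell (8 and 9 adjusted over the list alone), with a median of −0.02 (adjusted p = 0.627). At 4 d against 2 d 19 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.000176; adjusted p = 0.120 with an estimated correlation). Against 0 h, 19 rose and 3 fell at 4 d (23 and 3 adjusted over the list alone; median 0.24, adjusted p = 0.00659; adjusted p = 0.246 with an estimated correlation), and without batch B the median was 0.14 (adjusted p = 0.0738). At 6 d 22 rose and 4 fell (22 and 4 adjusted over the list alone; median 0.29, adjusted p = 0.00682; adjusted p = 0.283 with an estimated correlation), and at 8 d 21 rose and 4 fell (21 and 4 adjusted over the list alone; median 0.25, adjusted p = 0.00810; adjusted p = 0.308 with an estimated correlation). From 4 d to 8 d 4 rose and 4 fell (2 and 3 adjusted over the list alone), with a median of 0.08, −0.05 with median centring (adjusted p = 0.650).

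**Figure D4:**
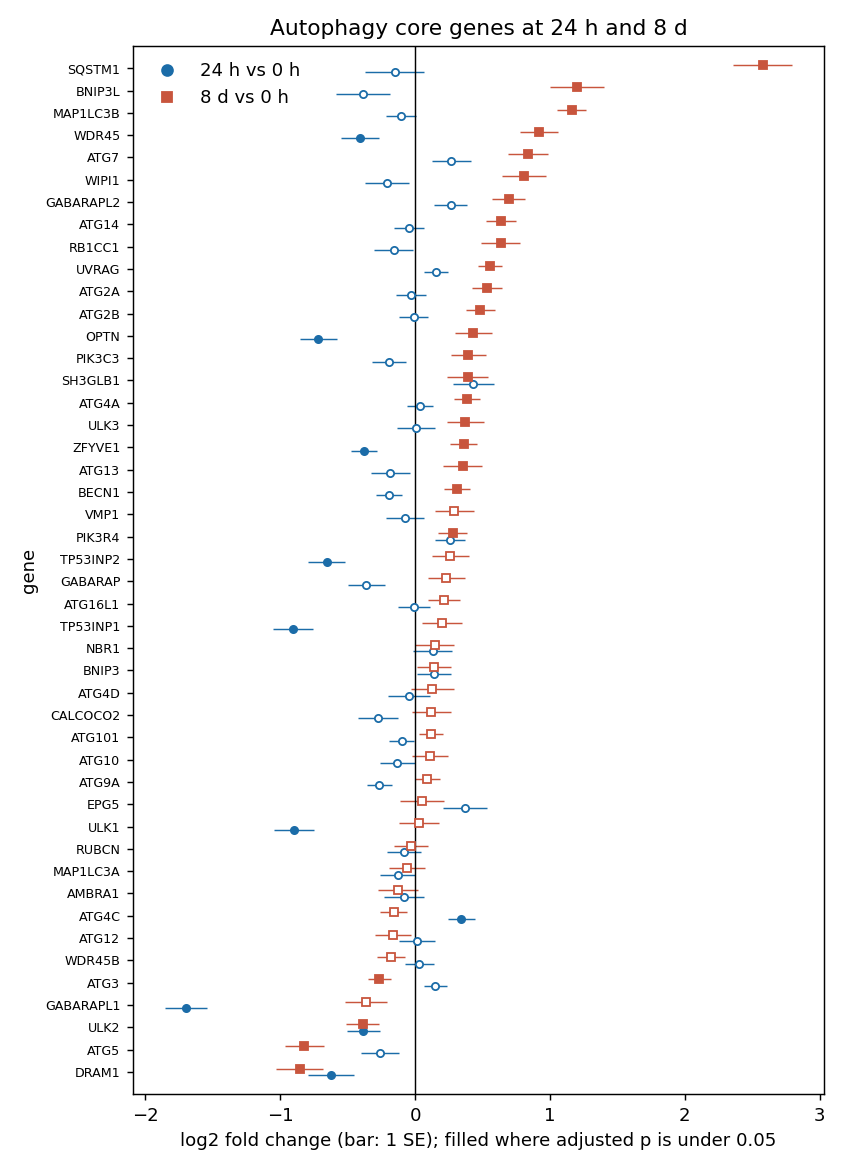
Log2 fold change ± 1 standard error of 46 autophagy genes at 24 h and at 8 d against 0 h, filled where the adjusted p is under 0.05 (n = 3 arrays per time point). The standard error comes from the fit of all 24 arrays.

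The difference between 8 d and 2 d was tested for the lists and the named genes. Of 51 lysosome genes, 41 were higher and 3 lower at 8 d (43 and 4 adjusted over the list alone), with a median of 0.69 (camera, adjusted p = 2.3e-12; adjusted p = 0.000388 with an estimated correlation). Of 46 autophagy genes, 23 were higher and 3 lower (23 and 4 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.000217; adjusted p = 0.142 with an estimated correlation), among them BNIP3L (1.30 ± 0.20) and MAP1LC3B (1.06 ± 0.11). STC2 (1.80 ± 0.11) and IGFBP4 (1.87 ± 0.15), low at 2 d, were higher at 8 d, and so was COL4A1 (1.80 ± 0.11), while FBLN1 was lower (−3.17 ± 0.22, −2.26 and −1.53 by its other probes). Of the 31 matrix genes, 9 were higher and 11 lower (9 and 11 adjusted over the list alone), with a median of −0.09 (adjusted p = 0.691).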

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

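The tests of the 4 d spread by time course and by batch, of the interferon genes by array and by culture, and of the fall of IL6 and CXCL8 at 24 h were chosen only after the result was seen, though the settings that leave out arrays were planned. IL6 moved in opposite directions at 2 time points: it was −1.26 against 0 h at 2 d and 5.41 at 8 d, a difference of 6.67 that passed its own test (limma, adjusted p = 1.5e-12). Its fall at 2 d, but not the difference, lost its call without 0 h A (−0.93, adjusted p = 0.0967), 2 d B (−1.14, 0.0575), batch A (−1.04, 0.1498) or batch B (−1.17, 0.157). Probes that name no gene, which the comparisons leave out, also held a signal: of 3619 above background, 824 changed at 8 d against 0 h (434 higher, 390 lower), 190 of them by at least 2-fold. That is a smaller share than among the named genes, of which 5221 of 11007 (47.4%) changed.

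The 3 arrays at 4 d lay apart on the first component, with batch B (46.7) among the 6 d and 8 d arrays (41.3 to 51.2), batch A at 33.6 and batch D at 24.9. Background correction and normalization are argued against as the cause, since the mitosis genes of 4 d B less those of 4 d D had a median of −0.67 in deposited values less the array median (−0.90 after both steps). A batch difference shared by all time points is argued against too, since B less D had a median of 0.26 over the other 7 time points. At 6 d, however, B less D was −0.82, near its value at 4 d, and at 8 d it was 0.43. A batch difference at 4 d and 6 d only is not excluded, since most of the other time points came before the main fall of the mitosis genes. Cultures at different points of the time course remain a possible explanation: across genes, 4 d B less 4 d D correlated with 6 d less 2 d (r = 0.48), below the bound of 0.5 set for it. Handling of single cultures cannot be told apart from this with 1 array per batch and time point.

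Interferon genes were higher at 4 d than at 2 d and at 8 d by the preset correlation (adjusted p = 0.182 and 0.0886 with an estimated correlation). One array as the source is argued against, since the lowest 4 d array (0.40, batch B; 0.95 in A and 1.07 in D) lay 0.29 above the highest of the 2 d and 8 d arrays. Probes near background are argued against too, since the 9 members above background on all 24 arrays had medians of 1.18 (4 d against 2 d) and −1.06 (8 d against 4 d), where all 19 had 0.50 and −0.77. Time in culture or handling stays open, as 0 untreated arrays after 0 h were used here.

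IL6 and CXCL8 fell at 24 h before their rise by 8 d. One array as the source is argued against, since 0 of 12 settings that leave out 1 array ended a call or turned a sign. Time in culture or handling stays open, with 0 untreated arrays after 0 h used here. An effect of 4-OHT or of the receptor part without RAS also stays open: estrogen receptor targets had a median of −0.30 at 24 h, and no arrays without RAS were used here. No biological explanation was tested for this pattern.

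For each comparison, the 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05, and in each the true split alone (1 of 10) gave as many genes. Every other split puts arrays of both time points on each side, so true changes enter the spread. Low counts in those splits were therefore likely from the start, and no conclusion is drawn from them. The true count and the highest other were 69 and 4 at 2 h, 499 and 1 at 8 h, 1979 and 0 at 24 h, 2581 and 0 at 2 d, 4834 and 6 at 4 d, 4988 and 0 at 6 d, 5221 and 0 at 8 d, 3969 and 1 for 4 d against 2 d, and 2239 and 60 for 8 d against 4 d. Among splits that part all 3 letter pairs, the highest other was 1 in the last 2 comparisons and 0 in the rest.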

How the results depend on the processing

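Tests with an offset of 50 were chosen only after the result was seen. Signal over background limits the dim genes: 26.7% to 30.1% of probes rose above it. Unless a value below shows it, the cause was not tested. The batch as a block moved no count by over 1.5 times (73 genes at 2 h, 561 at 8 h, 2088 at 24 h, 2646 at 2 d, 4890 at 4 d, 5067 at 6 d, 5268 at 8 d, 4017 for 4 d against 2 d and 2320 for 8 d against 4 d). With the block, the lists of senescence chromatin (−0.25, adjusted p = 0.0725), glycolysis (0.15, 0.0639) and epithelial markers (−0.33, 0.0629) lost their call at 2 d, IL6 gained one at 2 h (1.498), CDKN1A at 24 h (−0.38), CDKN2B at 8 h (0.72), BECN1 (0.26) and FOSL1 (0.39) at 8 d against 4 d, and it changed no other call of a list or of a gene named here.

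Median centring gave 23 genes at 2 h, 165 at 8 h, 1681 at 2 d, 2484 for 4 d against 2 d and 1289 for 8 d against 4 d. With it the median of all genes was −0.19 at 2 h, −0.13 at 24 h, −0.10 at 2 d, −0.12 at 6 d and −0.15 at 8 d. Among lists that passed with or without it, at 2 h it turned the medians of matrix (−0.0648), cholesterol (−0.0871), unfolded protein (−0.0949) and NF-kB genes (−0.0253), and at 24 h that of senescence chromatin (−0.0271). Medians of lists that passed in neither setting turned as well. At 2 h these were lysosome (−0.18) and smooth muscle (−0.12), and at 24 h cholesterol (−0.0933), glycolysis (−0.0400) and ribosomal proteins (−0.114). Others turned at 2 d, 4 d, 8 d and 8 d against 4 d. Array weights gave 333 genes at 2 h, 1478 at 8 h, 4716 at 24 h and 4575 at 2 d. The weights were uneven, with 7.44 for 24 h A against 1.40 for 24 h B and 0.346 for 24 h D. The batch D array had the lowest weight of its time point except at 4 d, where batch B did (0.206). Only the 2 time points compared gave 28 at 2 h, 4062 at 4 d, 3237 for 4 d against 2 d and 981 for 8 d against 4 d. That setting has fewer residual degrees of freedom and takes the spread from those arrays alone. It gave more genes than the main fit at 24 h (1991), 2 d (3230) and 6 d (5242), so fewer degrees of freedom alone do not account for the changes. A change of at least 2-fold, a stricter threshold by construction, left 22 genes at 2 h, 46 at 8 h, 227 at 24 h, 367 at 2 d, 1080 at 4 d, 1251 at 6 d, 1316 at 8 d, 688 for 4 d against 2 d and 300 for 8 d against 4 d.

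Leaving out an array or a batch gave from 1 (batch A) to 151 (batch D) genes at 2 h, 28 (A) to 577 (8 h D) at 8 h, 663 (A) to 1679 (D) at 24 h, 867 (A) to 2634 (D) at 2 d, 3102 (A) to 5027 (D) at 4 d, 3278 (A) to 4972 (D) at 6 d, 3676 (A) to 5188 (D) at 8 d, 1967 (B) to 4355 (D) for 4 d against 2 d and 855 (A) to 2659 (D) for 8 d against 4 d. Without 4 d B the counts were 4226 at 4 d, 3168 against 2 d and 2038 for 8 d against 4 d, and without 4 d D 4647, 3886 and 2070. The median of glycolysis and hypoxia at 2 h, near 0, was above it without any array or batch, from 0.004955 (0 h A) to 0.0568 (0 h D), and passed without 2 h A (0.0218) or batch A (0.0465). That of DNA replication at 2 h, which did not pass (−0.03), turned and passed without 2 h D (0.0915, adjusted p = 0.0295), and passed with its own sign without 0 h D (−0.123, 0.00679) or 2 h B (−0.119, 0.0360). At 8 d against 4 d it turned without batch D (0.0683, not passing; −0.439 without batch B).

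The autophagy list at 24 h (−0.10) passed with median centring (−0.26), no detection filter (−0.0918) and fry (−0.10), and leaving out an array or a batch gave −0.149 (24 h D) to −0.0599 (0 h D). Its medians of 0.24 at 4 d, 0.29 at 6 d, 0.25 at 8 d and 0.26 for 4 d against 2 d did not pass with a correlation estimated from the data. That test widens as the estimate rises above the preset 0.01. The 4 d median was 0.141 without batch B and 0.312 without batch D. A BeadChip block was not run, since the files used here name no BeadChip.

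Other probes turned the sign of these calls: KRT18 at 2 d (0.0865 and 0.122), 4 d (0.0129), 6 d (0.1498) and 8 d (0.0580), MUC1 at 6 d (0.0960) and 8 d (0.0453), RPL13 at 4 d (0.815) and at 4 d against 2 d (0.219), RPL8 at 4 d (0.301), 6 d (0.195), 8 d (0.416), 4 d against 2 d (0.161) and 8 d against 2 d (0.276), CCNE2 (0.0400) and SOD2 (0.0254) at 24 h, and NFKBIZ at 2 d (0.0271). Of these, RPL13 at 4 d and RPL8 at 8 d passed with the other sign.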

Other observations

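PHGDH, the first enzyme of serine synthesis, fell by 2.04 ± 0.31 at 6 d and by 2.20 ± 0.31 at 8 d. The unfolded protein and ATF4 list around it went both ways at 8 d (6 of 28 rose and 7 fell, 6 and 7 adjusted over the list alone; median −0.14, adjusted p = 0.522), with EDEM1, which takes part in breakdown of misfolded proteins, rising (0.92 ± 0.11). TM7SF2 (1.80 ± 0.14) and DHCR7 (1.28 ± 0.17), both enzymes of cholesterol synthesis, rose at 8 d. Of 19 cholesterol genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.45. By camera the adjusted p of the list was 0.0307, and 0.458 with an estimated correlation. That list lost its call without 0 h B (0.42, adjusted p = 0.0556), 8 d A (0.45, 0.0520) or batch A (0.37, 0.0643).

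Sugar, growth and ribosome genes held members that went both ways at 8 d. HK2 rose (1.77 ± 0.15) while SLC2A1, a glucose transporter (−1.01 ± 0.19), and PFKP, a phosphofructokinase (−0.94 ± 0.11), fell, and the 27 genes of glycolysis and hypoxia (10 rose, 7 fell; 10 and 7 adjusted over the list alone) had a median of 0.14, −0.12 with median centring (adjusted p = 0.379). Of 15 negative regulators of mTOR and PI3K, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.02, −0.08 with median centring (adjusted p = 0.360), PIK3IP1 (0.98 ± 0.18) and TSC1 (0.77 ± 0.12) among the rises. Of 34 cytosolic ribosomal protein genes, 8 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of −0.14 (adjusted p = 0.140), and the rise was of RPS15 (1.16 ± 0.14). Among the falls, RPL8 was −0.38 ± 0.10 by the probe used and 0.416 by its other probe (adjusted p = 0.0414), and lost its call without batch A (−0.32, 0.0915) or batch B (−0.35, 0.0638). Of 15 estrogen receptor targets, 8 fell and 5 rose (8 and 6 adjusted over the list alone), with a median of −0.32 (adjusted p = 0.436), among the rises CTSD, a lysosomal protease (1.30 ± 0.16), and PDZK1 (1.10 ± 0.12).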
